A study of Mus musculus with 6 samples.

How the data were processed

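RNA from C2C12 myotubes was measured on Arraystar mouse lncRNA arrays, with 3 control and 3 CoCl2 samples and 1 array per sample. Per the labels' protocols, cells were grown in 10% fetal bovine serum, differentiated in 2% horse serum and exposed to 200 uM CoCl2 for 48 h. Also per the labels' protocols, ribosomal RNA was removed from total RNA, the remaining RNA was amplified with random priming along the transcripts, and the product carried the dye Cy3. Samples were grouped by the treatment and title in the labels.

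The deposited scanner files hold spot intensities on a linear scale for 62939 spots, 61500 of them not control spots. Per the file headers, Agilent Feature Extraction 11.0.1.1 made the processed signal intensity by subtracting background with spatial detrending, and no normalization between arrays was applied. The files also give, per the file headers, the median intensity of each spot and of its local background, and flags of 0 or 1 for spots well above background, saturated or non-uniform. The authors' deposited value table holds values on the log2 scale for 60804 probes. Each of its columns correlated with its own array's log2 scanner signal (r 0.998 to 1.00), with column medians of 5.75 on every array and sorted values within 0.047 of each other, as quantile normalization between arrays would leave them. No gene centring was seen, and the tool behind that table is not given in the sources used here. It was used as an alternative only.

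Control spots and spots carrying an outlier flag (57 to 100 non-control spots per array) were left out, and no spot was saturated. Spots of a probe were averaged on the log2 scale. The log2 processed signal was then shifted by each array's 75th percentile over 60915 probes. A probe was tested if it was well above background on at least 3 of the 6 arrays, counting a probe with several spots when at least 50% of them were, which left 34839 probes. No negative-control probe was well above background on any array. Per array, 53.7%, 56.4% and 57.1% of probes were well above background in controls 1 to 3, and 50.9%, 55.8% and 57.6% in CoCl2 replicates 1 to 3.

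The CoCl2 and control groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. All adjusted p values come from limma. Means, SDs and fold changes are on the log2 scale, and a fold change is CoCl2 minus control. Tables and resampling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The fit was tested on simulated data with the real spread of the 34839 probes and 200 of them changed. It recovered 0% of changes of 0.5 on the log2 scale, 15% of those of 1 and 62% of those of 2, with 0% false calls. Simulations with so few changed probes face a stricter adjusted threshold than data with many.

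Scan days and scan starts were read from the files, and arrays with the same scan start were taken as sharing a slide. No slide identifier was read. On that basis control 1 was on slide 1 and control 2 on slide 2, both scanned on day 1. Control 3 and the CoCl2 arrays were on slide 3, scanned on day 2. Blocking by slide or by scan day therefore gives the same fold change, that of the CoCl2 arrays against control 3, with fewer residual degrees of freedom than the unblocked fit. With slide as a block each control is fitted exactly. The 2 residual degrees of freedom then come from the CoCl2 arrays alone, and the p values carry no spread between control cultures. A call lost there can reflect this loss and need not mean a smaller change.

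The files do not pair 59064 of the probes with a gene. Another 1836 carry a lincRNA name with a strand sign and no gene symbol, and 15 carry a RefSeq accession. All 15 accessions matched a table of RefSeq genes for assembly GRCm38.p6, which was used for names alone, since the array design is annotated to mm9. No coordinates are given for this reason. The count of changed lncRNA probes therefore covers the lincRNA-named probes, and the count of changed coding probes the RefSeq-named panel. The 20 gene lists fixed for the tissue and treatment hold 433 entries. The HIF target list has 1 of its 32 members named on the array (Tfrc) and the glycolysis list 2 of 18 (Gapdh and Pgk1), while the other 18 lists have none, so no list was tested.

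The rule for named genes, fixed before the data were examined together with the design and the alternatives listed at the end, took the largest changes with a symbol among probes past the threshold, well above background on all 6 arrays and with separated groups. Among symbols it gives Gk, Hprt, Gusb and G6pd2. The rest of the RefSeq panel is reported because these are the genes that can be named, a choice made after the files were seen, and so is the use of the GAPDH and PGK1 control-type spots, each printed 10 times, in a fit beside the tested probes. Among lincRNA names the same rule was limited to 2 rises and 2 falls. The brightness-matched lists, strand pairs, detection counts and neighbour tests were also chosen after the data were seen, with the predictions for the array position and control level of neighbours written before those results.

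The alternatives were quantile normalization, median scaling, normexp background correction with offset 50 followed by quantile normalization, the deposited values, no filter, a filter on all 6 arrays, an intensity trend with robust estimation, array weights, blocks by replicate number, slide and scan day, unadjusted p, and leaving out each array. The files hold no mean signal column, so normexp used the median signal. The median log2 fold change over all tested probes was 0.11 in the main scaling, 0.07 under quantile normalization, 0.12 under median scaling and 0.05 under normexp.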

Results

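C2C12 is a mouse myoblast line that fuses into multinucleated myotubes when serum is lowered. The cells were differentiated in 2% horse serum, and one group received cobalt chloride (CoCl2, 200 uM) for 48 h before collection. CoCl2 is a widely used chemical mimic of hypoxia, because cobalt ions stabilise hypoxia-inducible factors. The study's title places the question in the toxicity of CoCl2 and its relation to long noncoding RNA (lncRNA) levels. RNA of 3 control and 3 CoCl2 cultures, described in the labels as independent experiments, was hybridised to 6 one-colour lncRNA arrays that also carry protein-coding probes. Between 50.9% and 57.6% of the 60915 scaled probes were well above background on an array, and 34839 probes were tested. The precision of each value is limited by the 3 arrays per group.

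The transcript profiles of CoCl2 and control myotubes differed broadly. Of the 34839 probes tested, 16580 (47.6%) passed an adjusted p of 0.05 in limma, 8763 of them higher and 7817 lower after CoCl2. The changed probes differed by a median of 2.08-fold, and 4314 were at least 2-fold higher and 4587 at least 2-fold lower. Changes of at least 8-fold were fewer, with 272 probes higher and 684 lower. Of the changed probes, 893 were well above background on all 3 control arrays alone and 585 on all 3 CoCl2 arrays alone. The size of such changes is uncertain, and how many of them are among the 8-fold changes was not counted. The balance of the 2-fold changes depended on the processing: with slide as a block 2475 were higher and 2426 lower, normexp background correction gave 2608 higher and 3150 lower, and the filter on all 6 arrays gave 3372 higher and 2781 lower. The CoCl2 and control arrays did not overlap for 20715 of the 34786 probes with 6 values (59.5%), where chance gives 10% for 3 arrays against 3. Almost all of these probes carry only an array ID that the files do not pair with a gene, so their transcripts are not named here.

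The 6 arrays separated by treatment along the first principal component, which held 85.2% of the variance. By their scan starts, controls 1 and 2 were each taken to be on a slide of their own. Control 3 was taken to share slide 3 with the 3 CoCl2 arrays, and shared their scan day. With slide as a block, which compares the CoCl2 arrays with control 3 alone, 5450 probes passed (2788 higher and 2662 lower), and 5291 of these were among the 16580. With scan day as a block 7510 passed. The slide block has 2 residual degrees of freedom, all from the CoCl2 arrays, so its calls carry no spread between control cultures. Of the 16580 probes, 16579 had a value on slide 3 and all of those differed in the same direction there, a comparison that uses the same CoCl2 arrays and is not independent.

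**Figure D1:**
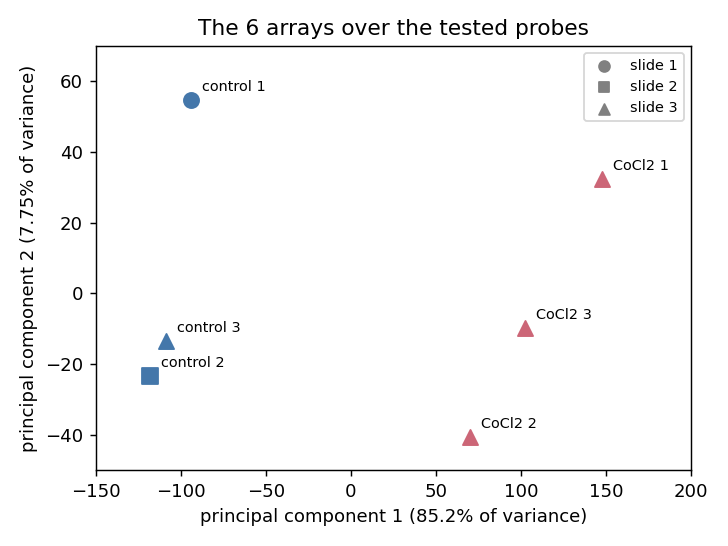
Scores of the 6 arrays on principal components 1 (horizontal) and 2 (vertical) of the scaled log2 signals. Each point is an array, blue for control and red for CoCl2, and its shape gives the slide inferred from the scan starts. Control 3, on slide 3, lies at -108.5 on component 1 beside control 2 at -117.9, while the CoCl2 arrays of slide 3 lie between 70.2 and 147.6.

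The probes that the files identify by a RefSeq accession cover 15 genes, mostly metabolic and housekeeping genes, and the sharpest change among them was a loss of Gusb. Gusb, which encodes the lysosomal enzyme beta-glucuronidase, was 7.87-fold lower after CoCl2 (log2 fold change -2.98, SE 0.22, adjusted p 8.1e-05, lower in all 3 CoCl2 arrays than in any control). The rule for named genes required such a separation, so it is not further evidence. G6pd2, a retrotransposed copy of the glucose-6-phosphate dehydrogenase gene, was 2.18-fold lower (log2 fold change -1.12, SE 0.17, adjusted p 0.00169). Gk, which encodes glycerol kinase, rose 2.01-fold (log2 fold change 1.01, SE 0.15, adjusted p 0.00153), and Hprt, of the purine salvage pathway, rose 1.81-fold (log2 fold change 0.85, SE 0.19, adjusted p 0.00939). G6pd2 has a near-identical parent gene, so its probe's signal is uncertain as to which of them it reports.

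With slide as a block Gusb was at -2.98 (adjusted p 0.0217, range over the alternatives 1.5e-07 to 0.0217) and G6pd2 at -1.19 (adjusted p 0.0459, range 6.9e-06 to 0.0459). Gk and Hprt no longer passed with that block, at 0.84 (adjusted p 0.0569, range 2.5e-05 to 0.0569) and 1.07 (adjusted p 0.0747, range 5.5e-05 to 0.0747). The Hprt fold change was larger with that block than the 0.85 of the main fit. Hprt was at 0.49 under quantile normalization and Gk at 0.60 under normexp background correction, and both still passed there.

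The other 10 measured panel genes did not pass. The log2 differences were 0.52 (SE 0.21) for the ribosomal protein gene Rpl13a, 0.28 (SE 0.15) for the chaperone gene Hsp90ab1, 0.12 (SE 0.17) for the transferrin receptor gene Tfrc, -0.45 (SE 0.18) for the tubulin gene Tuba1b, -0.39 (SE 0.24) for the actin gene Actb, -0.38 (SE 0.14) for the splicing-related gene Nono, -0.30 (SE 0.23) for the TATA-binding protein gene Tbp and -0.13 (SE 0.22) for the beta-2-microglobulin gene B2m. Ppia, encoding cyclophilin A, differed by 0.00 (SE 0.16), and Gapdh by 0.44 (SE 0.19). With slide as a block Tuba1b was at -0.17 and Actb at -0.04, and Actb was at -0.12 without control replicate 1. Ldhal6b, a lactate dehydrogenase-like gene, was not well above background on any array. Most of these genes are bright, and the 3484 brightest tested probes were shifted by a median log2 of 0.33 after CoCl2 in the 75th-percentile scaling and by 0.04 under quantile normalization. Under quantile normalization 8 panel genes passed, with Tuba1b at -0.81 (adjusted p 0.00168), Actb at -0.59 (adjusted p 0.0333), Nono at -0.51 (adjusted p 0.0307) and B2m at -0.46 (adjusted p 0.024) among the 6 lower ones, and Ppia, Hsp90ab1 and Tfrc took the opposite sign. Over the alternatives the adjusted p of Tuba1b ranged from 0.000534 to 0.6, that of Actb from 0.0175 to 0.936, that of Nono from 0.00145 to 0.256 and that of B2m from 0.0137 to 0.952.

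**Figure D2:**
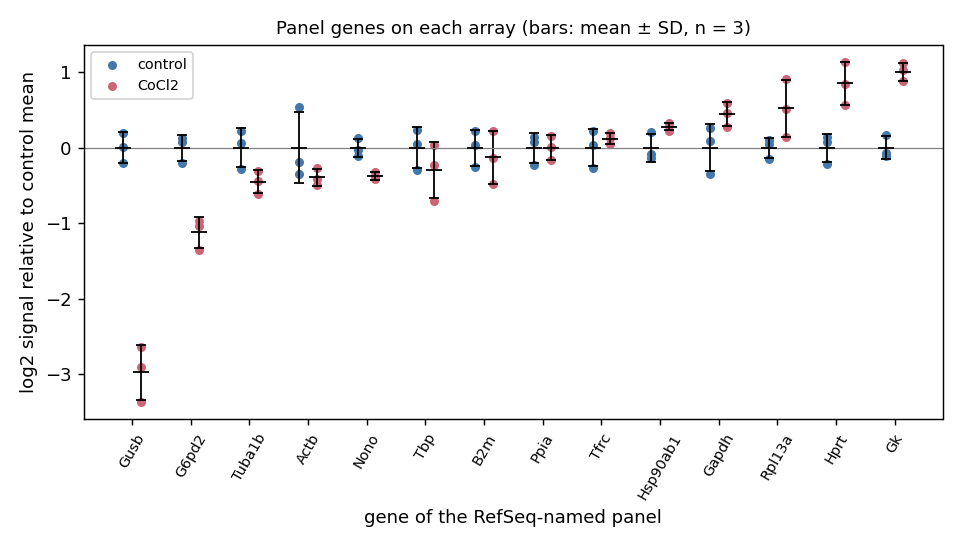
Log2 signal of the 14 measured panel genes on each array (vertical axis), relative to the mean of the 3 controls, with genes ordered along the horizontal axis by fold change; points are arrays, blue for control and red for CoCl2, and bars are mean ± SD with n = 3. Gusb lies lowest at a mean of -2.98 and Gk highest at 1.01, and the genes between G6pd2 and Hprt did not pass in this scaling.

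The probes named for Pgk1 and Gapdh, both genes of glycolysis, were higher after CoCl2, although the RefSeq-named Gapdh probe did not pass. These are the only members of the glycolysis list named on the array, and the list itself was not tested. The array's control-type spots named for Pgk1, encoding phosphoglycerate kinase, and for Gapdh, encoding glyceraldehyde-3-phosphate dehydrogenase, were read after the files had been seen, because few other probes carry a gene name. The mouse Pgk1 probes rose 1.92-fold at the 3′ end (log2 fold change 0.94, SE 0.16, adjusted p 0.00257) and 3.1-fold at the 5′ end (1.63, SE 0.20, adjusted p 0.000693). The mouse Gapdh probes rose 1.67-fold at the 3′ end (0.74, SE 0.20, adjusted p 0.0199) and 2.15-fold at the 5′ end (1.1, SE 0.17, adjusted p 0.00169). All 4 mouse probes kept their direction under every alternative tried, although the log2 fold changes of the bright ones fell under quantile normalization, to 0.58 for the Pgk1 3′ probe and 0.42 for the Gapdh 3′ probe.

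With slide as a block the mouse Pgk1 probes were at 1.14 (adjusted p 0.0382, range over the alternatives 1.8e-05 to 0.0382) and 1.5 (adjusted p 0.0238, range 2.6e-06 to 0.0238). The mouse Gapdh 3′ probe was at 1.08 (adjusted p 0.0487) and lost its call without control replicate 2 (0.76, adjusted p 0.0569), without control replicate 3 (0.57, adjusted p 0.0638) and without CoCl2 replicate 3 (0.73, adjusted p 0.0694), within a range of 8.6e-05 to 0.0694. The RefSeq-named Gapdh probe, the brightest of the Gapdh probes, did not pass (adjusted p 0.0956), so the probes of this gene disagree on the call and agree on the sign. That probe passed with array weights (0.66, adjusted p 0.00086) and without control replicate 1 (0.57, adjusted p 0.0491), and was at 0.12 under quantile normalization (adjusted p 0.388, range over the alternatives 0.00086 to 0.388). It was at 0.27 without control replicate 3 and at 0.79 with either the slide or the scan day block. Gapdh has many near-identical pseudogenes, which these probes may also read. The rat and human probes for both transcripts were read from the same samples on the same arrays, so they are not independent evidence. They were higher as well, by log2 0.79 to 2.26 in the main scaling and by 0.41 to 2.26 under quantile normalization. Of these, the human GAPDH 3′ probe no longer passed with slide as a block, where it was at 0.98 (0.79 in the main fit). The human GAPDH 5′ probe no longer passed with scan day as a block, where it was at 1.08 (1.18 in the main fit).

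**Figure D3:**
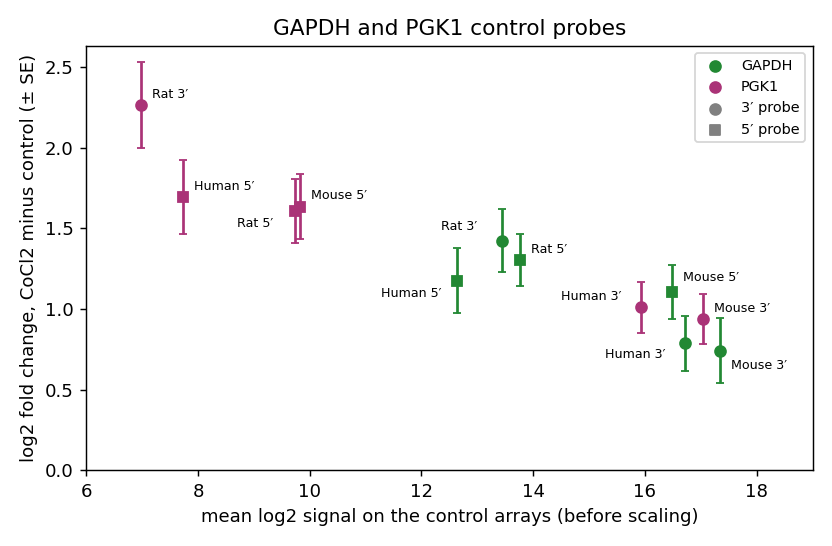
Log2 fold change of the 12 control-type probes named for GAPDH (green) and PGK1 (purple), with its SE (vertical axis), against the mean log2 signal on the control arrays before scaling (horizontal axis); circles are 3′ and squares 5′ probes, and the label gives the species of the probe. The rise is 2.26 for the dimmest probe and 0.74 for the brightest.

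Long intergenic noncoding RNAs (lincRNAs) were changed in both directions, with more rises than falls in the unblocked fit and 14 rises against 17 falls with slide as a block. Of the 1836 probes whose names mark them as lincRNA probes, 361 (19.7%) were detected well enough to be tested, and 123 of these passed, 85 higher and 38 lower. At least 2-fold changes were found for 44 higher and 22 lower probes. The probes named for mouse lincRNAs gave 29 higher and 16 lower of 128 tested, those named for human lincRNAs gave 46 higher and 17 lower of 204 and those named for lincRNA exons gave 10 higher and 5 lower of 29. What a human lincRNA name stands for on this mouse array is not given in the sources used here, so 63 of the 123 changed probes, and the shares below, rest partly on names of unknown meaning. Changes were found in 34.1% of the lincRNA-named probes, against a median of 46.5% (95% range 41.3% to 51.5%) in 10000 random lists matched on brightness, none of which had a smaller share. The lists drew ID-only probes, those of the ID series marked UP left out, one by one from the same arrays. Their range therefore carries no spread between cultures and no shared change between probes. The lower share was that of the mouse names (35.2% against 46.9%) and human names (30.9% against 46.1%). The exon names were at 51.7% against 48.3% in their matched lists (95% range 31.0% to 65.5%). With 29 tested probes, whether the exon names differ from the other names cannot be told.

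The share of changed lincRNA-named probes that were higher was 69.1%, against a median of 50% (42.4% to 57.6%) in the matched lists. That share fell to 45.2% with slide as a block, where 31 lincRNA-named probes passed (14 higher and 17 lower), and to 47.8% with scan day as a block (22 higher and 24 lower of 46). Those blocks changed which probes passed and not their direction, since all 123 changed lincRNA-named probes kept their direction against control 3. The matched range was drawn for the unblocked fit only, so it does not apply to the blocked shares. With 1 array left out the share that were higher ranged from 58.8% to 73.3%. Without CoCl2 replicate 3 the count of changed lincRNA-named probes was 77, and limma's array weights raised it to 234.

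The lincRNA-named probes with the largest falls among those well above background on all 6 arrays were humanlincRNA0065-_P1, 3.97-fold lower (log2 fold change -1.99, SE 0.13, adjusted p 5.0e-05), and mouselincRNA0453+_P1, 3.6-fold lower (-1.85, SE 0.15, adjusted p 0.000123). The largest rises were those of mouselincRNA0543-_P1, 7.3-fold (2.87, SE 0.71, adjusted p 0.0141), and MM9LINCRNAEXON10569-_P1, 7.18-fold (2.84, SE 0.57, adjusted p 0.00581). The rule that picked these 4 also required that the CoCl2 arrays did not overlap the controls, so that separation is not further evidence. Both falls also passed with slide as a block (adjusted p 0.0165 and 0.0184, the highest over the alternatives, which reached down to 1.4e-07 and 2.9e-07). Both rises did not, at 3.36 (adjusted p 0.0702, range 2e-05 to 0.0741) and 2.93 (adjusted p 0.0872, range 1.6e-05 to 0.0872). The rise of mouselincRNA0543-_P1 also lost its call without control replicate 2 (2.39, adjusted p 0.0543) or control replicate 3 (2.62, adjusted p 0.058), and was larger without control replicate 1 (3.59, adjusted p 0.006). With replicate number as a block the rises of mouselincRNA0543-_P1 and MM9LINCRNAEXON10569-_P1 kept their size, with SEs of 0.21 and 0.15 (adjusted p 0.000602 and 0.000315).

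Some transcripts were detected in a single condition. In CoCl2 myotubes 612 probes were well above background on all 3 arrays and on no control array, 8 of them lincRNA-named. The reverse held for 913 probes, 11 of them lincRNA-named. Among the other ways to divide the 6 arrays into sets of 3, the most probes detected on one set alone was 162. Each of those divisions mixes the groups, so a group difference of any cause lowers its count, and 162 is not a chance level. A probe that is not well above background has only an upper bound there, so these counts do not show that a transcript was absent.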

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

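Both values below were picked out because control spots outside the comparisons, on probes with no named mouse target, were brighter on the CoCl2 arrays than on the controls, and both were looked for after the data were seen. Of 10 such control probes tested, these 2 passed and 8 did not, the latter including DCP_1_1 at 0.006 and ERCC-00062_278 at 0.70 (limma adjusted p 0.0654). Among the 34839 tested probes 47.6% passed, so 2 of 10 is no excess. The 2 that passed were dim, with control means of -3.57 (ERCC-00012_90) and -3.29 (ETG10_13482) relative to each array's 75th percentile. The control probe ERCC-00012_90 was higher after CoCl2 by 1.12 on the log2 scale (SE 0.19, limma adjusted p 0.00265, well above background on 4 of 6 arrays, every CoCl2 array above every control). The control probe ETG10_13482 was higher by 1.03 on the log2 scale (SE 0.25, limma adjusted p 0.013, well above background on all 6 arrays, every CoCl2 array above every control).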

How the results depend on the processing

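Of 71 counts under 18 alternatives, 57 stayed within 1.5 times the main count, and the cause of the others was not tested except where stated. Array weights raised the changed probes from 16580 to 26511, the lincRNA-named ones from 123 to 234 and the panel genes from 4 to 11, with weights of 0.214 for control 1 and 16.8 for CoCl2 replicate 3. The slide block gave 5450 changed probes, 4901 changed at least 2-fold (main 8901), 31 lincRNA-named and 2 panel genes. The scan day block gave 7510 and, for lincRNA names, 46. Both blocks leave a single control on the shared slide. Normexp gave 5758 probes changed at least 2-fold and 9 panel genes, quantile normalization 8 panel genes and unadjusted p 7. Leaving out 1 array gave 11491 to 17538 changed probes, 7637 to 10330 at least 2-fold, 77 to 146 lincRNA-named and 4 to 6 panel genes.

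Of 514 gene or probe values, 462 kept direction and side of the threshold, 25 newly passed, 13 no longer passed and 14 changed sign, for genes that had not passed. Of those 14, 1 passed with the opposite sign, Ppia under normexp (adjusted p 0.0316, range over the alternatives 0.0316 to 0.998). Under quantile normalization Ppia was at -0.35, Hsp90ab1 at -0.10 and Tfrc at -0.25. Under normexp these were -0.33, -0.078 and -0.25. B2m was at 0.0198 with array weights and 0.13 with either the slide or the scan day block. With 1 array left out Ppia ranged from -0.11 to 0.086, B2m from -0.30 to 0.0472 and Tfrc from -0.0117 to 0.2335.

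Same-numbered control and CoCl2 arrays had correlations of deviations from their group means of 0.30, 0.36 and -0.03. Controls 1 and 2 each correlated best with the CoCl2 array of their own number. Control 1 with CoCl2 replicate 2 gave -0.37, and control 2 with CoCl2 replicate 1 gave -0.30. Control 3 correlated best with CoCl2 replicate 2 (0.18). The labels do not say what the numbers share, so they were not taken as pairs in the main fit, and a pairing of numbers 1 and 2 stays open. The replicate block gave 18765 changed probes, 9088 at least 2-fold, 148 lincRNA-named and 5 panel genes. Gene list shifts were not run, since 3 listed genes are named, and the panel has no deposited values. Dim probes limit the lincRNA result, since 19.7% of them could be tested.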

Other observations

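All tests below were added after the data were first seen. Those of array position and control level for neighbouring ID numbers had their predictions written before their results, and the others were chosen after the result was seen. The lincRNA-named probes cover both strands of 876 names, and 35 of these had both strands tested. In 5 of the 35 both strands changed, 4 of them in the same direction, in 16 a single strand changed and in 14 neither. Independent strands would give 4.71 with both changed (Fisher's exact test p 1). Across the 35 names the fold changes of opposite strands had r 0.12 (permutation p 0.469, two-sided). Probes of the ID series marked UP, whose meaning is not given in the sources used here, changed upward more often than the other ID-only probes of matched brightness, with 98 higher and 41 lower of 283 tested (70.5% higher, against 51.6% in the matched lists, range 43.1% to 60%). With slide as a block 40 of the UP probes passed, 28 higher and 12 lower.

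The broad difference between CoCl2 and control arrays was set against a scan batch, since control 3 alone shares the inferred slide and the scan day of the CoCl2 arrays. Over 12276 probes called without control 3, this array lay at a median of 0.0288 on a scale from controls 1 and 2 (0) to CoCl2 (1), with quartiles of -0.08 and 0.15, which argues against the batch as the whole cause. The other 9 splits of the 6 arrays called at most 0 probes against 16580, and 1 of the 10 splits reached that count, the real one. This cannot decide the question, since 10 splits are too few for a share under 0.05. Each other split also mixes the groups, so a group difference of any cause adds to its residual spread and lowers its calls. The design names CoCl2 as the difference between the groups, which remains a hypothesis for the cause, and smaller batch effects on single probes were not excluded.

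The brightest GAPDH and PGK1 probes rose less than the dimmer ones, though not in strict order. Array scaling does not account for this, since the rat GAPDH 3′ probe rose by 0.68 more than the mouse one (SE 0.14) in the main scaling and by 0.81 more under quantile normalization. Signal compression at high brightness stays open, since that difference of 0.68, and one of 1.33 (SE 0.38) for the PGK1 3′ probes, are the pattern itself and not a separate test of it, and with slide as a block they shrank to 0.47 and 0.61. A loss of 5′ RNA ends in the control cultures stays open as well, and predicts a larger rise at the 5′ end. The 5′ minus 3′ difference was 0.36 (SE 0.10) and 0.39 (SE 0.25) for mouse and human GAPDH. It was 0.70 (SE 0.28) and 0.69 (SE 0.32) for mouse and human PGK1, but -0.12 (SE 0.17) for rat GAPDH and -0.66 (SE 0.40) for rat PGK1. The human GAPDH value and both rat values were within 2 SE of 0. With slide as a block the mouse and human differences shrank to 0.23 and 0.10 for GAPDH and to 0.36 and 0.37 for PGK1. The rat differences were then -0.24 for GAPDH and -0.31 for PGK1. Pseudogenes or mismatched probe sequences were not tested and stay open, as does a change in transcript form after CoCl2.

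Probes with consecutive ID numbers changed together, with r 0.15 between the fold changes of 21880 such pairs, above the highest of 1000 shuffles of the ID order (0.02). Among the 5373 pairs in which both probes changed, 60.5% had the same direction. Position on the array was argued against, since probes printed next to each other had r 0.0034. ID numbers that follow a gene or transcript order are a candidate explanation, since control levels of consecutive numbers also correlated (r 0.0465, highest shuffle 0.02), though weakly. No table used here gives the genes behind the numbers, and transcripts regulated together stay open as well.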
